A study of Mus musculus with 5 samples.

How the data were processed

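Testis of 3-month-old mice was used for 5 libraries. The RNA libraries were made from polyadenylated RNA of wild-type and Taf7l knockout males, with 6 RNA extracts pooled per genotype and 8 µg of pooled RNA used, per the labels' protocols. The 3 ChIP libraries are labelled wild type, while the labels' shared ChIP protocol names wild-type and knockout chromatin; they were taken as wild type. Each was made from 1 mg of chromatin sheared to fragments of 175 to 225 bp, with 4 µg of TAF7L or Pol II antibody or 8 µg of IgG, per the labels' protocols. The submitters' processing notes name Bowtie for the ChIP libraries, Bowtie, TopHat and Cufflinks for the RNA libraries and the build mm9. Versions, the peak caller and the use of the IgG library are not given in the sources used here.

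The authors deposited 2 tables. The deposited expression table has 55350 transcripts, of which 47041 have a gene name, each with a position and, per the file headers, a mean and a standard deviation of an expression signal for each genotype. The header names no unit; the signal sums to different totals in both libraries and is on the scale of RPKM. What the mean and standard deviation were taken over is not given in the sources used here. The largest ratio of standard deviation to mean was 8.00 in the wild type and 7.75 in the knockout, as 1 non-zero value among 64 and 60 would give. They were therefore read as a spread over parts of 1 library, which is technical and no replicate spread. Per the file headers the table also holds a log2 ratio of wild type to knockout and a ratio of standard deviation to mean. The authors' log2 ratio matched one computed with 0.001 added to each signal, within 0.02, for 99.99% of transcripts with a mean of at least 1. The deposited binding table has 55419 transcripts with a TAF7L and a Pol II score in promoter, proximal and distal classes, per the file headers. The header defines neither the score nor the distances, and 0 was read as no assigned signal. Of its transcripts, 69 were not in the expression table.

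Depth was read from labels and values. The labels give 100 to 200 M reads (1 M being 1e+06 reads) per RNA library. If the spread over parts is counting error, 10 single-exon genes gave a median depth of 126 M reads in the wild type (range 69.4 to 160) and 88.2 M in the knockout (58.3 to 116). The median ratio of standard deviation to mean, in the library with the higher signal, was 0.128 for genes with a mean of at least 1. No depth is given for the ChIP libraries.

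The comparison was fixed before the data were examined as gene-level FPKM or RPKM, with transcript values summed or the row with the highest mean used for gene-level rows. The transcript values turned out not to be split between isoforms. In 1343 pairs of transcripts with the same span, the lower value was 0.936 of the higher in the median. The transcript with the highest mean was therefore used for each gene. Gene symbols were matched with older symbols in a RefSeq table of GRCm38, used for names only. This merged 680 names and gave 21720 genes from 47041 transcripts, and left 8309 transcripts without a gene name out of the comparisons. Overlapping genes and near-identical copies could not be separated, and strand was not stated.

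Change was log2((knockout + 1)/(wild type + 1)), which understates the change of low genes, and genes with a mean of at least 1 were compared. With 1 library per group no test across samples was possible. A gene was called higher or lower at 2-fold, and no p-value is given. For 20 gene lists fixed before the data were examined, the median change was set against 10000 random lists of the same size matched on 20 bins of mean expression. The lists cover the targeted gene and its relatives, TFIID, sperm chromatin packaging, acrosome, tail, energy metabolism, ion channels, postmeiotic regulators, meiotic prophase, piRNA pathway, spermatogonia, Sertoli, Leydig, peritubular, endothelial and blood cells, leukocytes, epididymis, adipocytes, stress and housekeeping genes. Tbp, Tbpl1 and Gtf2a1l stand in 2 lists each. Shares of genes have 95% Wilson intervals, which cover counting over genes only. A gene had a promoter score when any of its transcripts did, and shares were set against 10000 draws of genes matched on 20 bins of wild-type signal or of the Pol II score. Draws matched on both, with 10 bins of wild-type signal in combination with the 20 of the Pol II score, were added after the data were seen.

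Genes were named by a rule fixed before the data were examined. It takes the 12 largest increases and 12 largest decreases, the most abundant member and the largest increase and decrease of each list, every relative of Taf7l, and the 10 highest TAF7L promoter scores. Of the 24 largest changes, examples are given, and some genes that the rule takes are not reported here. Tnp1, Tnp2 and the genes named with the filter on the spread over parts were chosen after their values were seen.

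The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with seed 1. They were tested on simulated data over 12432 genes for the knockout against wild-type comparison. Of 100 unchanged lists 4 fell outside the central 95%, and of 100 lists shifted by 0.5 or by 1 on the log2 scale 94 and 100 did. Of 100 planted 3-fold rises 100 were called and of 100 planted 3-fold falls 89. Of 12232 unchanged genes 0.376% were called. The simulated lists varied by independent noise that shrank with mean signal. The genes with planted or no changes varied by the spread over parts, scaled to the error of its mean. The simulated knockout took the smaller error of both libraries, enlarged for planted rises. The share of unchanged genes called can therefore be understated. Planted changes were placed only in genes above a set wild-type signal. In the library with the higher signal these genes had a standard deviation over parts below the mean. These shares leave out variation between animals or pools and joint variation of genes within a list. They give no rate of false calls for the genotypes. Alternatives were pseudocounts of 0.1 and 5, a minimum mean of 5 or none, thresholds of 1.5-fold and 3-fold, rescaling to a median change of 0 or to the same upper quartile, and promoter scores at or above the median of their list. Summed and median transcripts, the filter on the spread over parts, the proximal class and the promoter class of the expressed transcript were added after the data were seen.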

Results

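Testes of 3-month-old mice were profiled in 5 libraries. Messenger RNA was sequenced from wild-type testis and from testis of males lacking Taf7l, an X-linked paralogue of the TFIID subunit gene Taf7. Each of these 2 RNA libraries was made from a pool of 6 extracts. Chromatin of wild-type testis was immunoprecipitated with antibodies to TAF7L and to RNA polymerase II (Pol II), and with non-specific IgG, in 1 library each. No condition had a replicate library, so differences are described by size and have no replicate check. The RNA libraries held 100 to 200 M reads each (1 M being 1e+06 reads), per the labels. The expression table gives a signal per transcript, and the binding table gives TAF7L and Pol II scores per transcript in promoter, proximal and distal classes.

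The targeted gene was lower in the library labelled knockout. Taf7l (chromosome X, 130994654 to 131011029, mm9) had a signal of 13.2 in the wild type and 2.04 in the knockout, a log2 change of -2.22. The standard deviations over parts of each library were 1.56 and 0.60. The remaining signal was not placed relative to the deleted part of the gene, which the sources used here do not give. Taf7, which encodes the ubiquitous TFIID subunit, had a signal of 4.46 in the wild type and 8.41 in the knockout. The related gene 4933416C03Rik (Taf7l2) had signals of 64.9 and 81.8.

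To describe how loss of Taf7l was associated with testis transcripts, the RNA libraries were compared gene by gene. Genes of late spermatids, such as the protamine genes, were lower in the knockout library, while markers of Sertoli cells, spermatogonia and macrophages were higher. Of 12432 named genes with a mean signal of at least 1, 915 were at least 2-fold higher and 909 at least 2-fold lower. The median log2 change of all genes was 0.40. Rescaling the knockout library to a median change of 0 gave 128 higher and 1583 lower genes, so that the share of lower genes among those past 2-fold moved from 49.8% to 92.5%. Prm1, Prm2, Tnp1 and Tnp2 together made up 11.5% of the total signal of named genes in the wild type and 2.21% in the knockout. Across genes, which are not independent replicates, the log2 signals of both libraries had a Pearson r of 0.918.

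Genes for packaging of sperm chromatin showed the lowest list median. Prm1 and Prm2, the protamines that replace histones in the sperm head, had wild-type signals of 17005 and 16972 and knockout signals of 2991 and 2341, log2 changes of -2.51 and -2.86. Of 15 measured members, 9 were at least 2-fold lower and none was at least 2-fold higher, a count that held after rescaling. The list median was -1.32, or -1.72 relative to the median of all genes, at the 0 percentile of 10000 random lists matched on mean expression. Rnf8, a ubiquitin ligase of histone removal, had the largest positive value, with signals of 10.2 and 19.2. The marker list of Sertoli cells, measured in the same libraries, had a median of 1.03.

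Genes of the acrosome, the secretory vesicle of the sperm head, and of the sperm tail were also lower. In the acrosome list 12 of 30 members were at least 2-fold lower and 1 was at least 2-fold higher. The median was -0.84, at the 0 percentile of matched lists. Fam170b fell most, from 121 to 40.3, whereas Tex101, which encodes a germ cell surface protein, rose from 40.3 to 108 and was within 2-fold after rescaling. Crisp2, the most abundant member, had signals of 641 and 414. In the tail list 14 of 33 members were at least 2-fold lower and none higher, with a median of -0.70 at percentile 0.03. Smcp, which encodes a cysteine-rich protein of the mitochondrial sheath, fell from 2689 to 426. Meig1 had signals of 1783 and 1364 and Rsph1, a radial spoke gene, 600 and 843.

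Sperm energy metabolism and signalling genes followed. Of 21 metabolic genes, 8 were at least 2-fold lower, and the median of -0.60 lay at percentile 1.01. Gapdhs, the glycolytic enzyme specific to sperm, fell from 704 to 144. Ldhc, the lactate dehydrogenase of male germ cells, had 2666 and 2307, and the glucose transporter gene Slc2a3 had 193 and 311. Of 24 ion channel and signalling genes, 12 were at least 2-fold lower, with a median of -0.83 at the 0 percentile. Tssk3, a testis-specific serine kinase gene, fell from 212 to 40.3. Pgp, the most abundant member, had 924 and 629, and Ppp3r2 had 122 and 135. Postmeiotic transcription regulators had 4 of 20 members at least 2-fold lower and a median of -0.26 at percentile 3.07, inside the central 95% of matched lists. Spz1 fell from 819 to 221, whereas Ybx2 had 1063 and 969 and Mybl1 9.55 and 16.2.

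**Figure D1:**
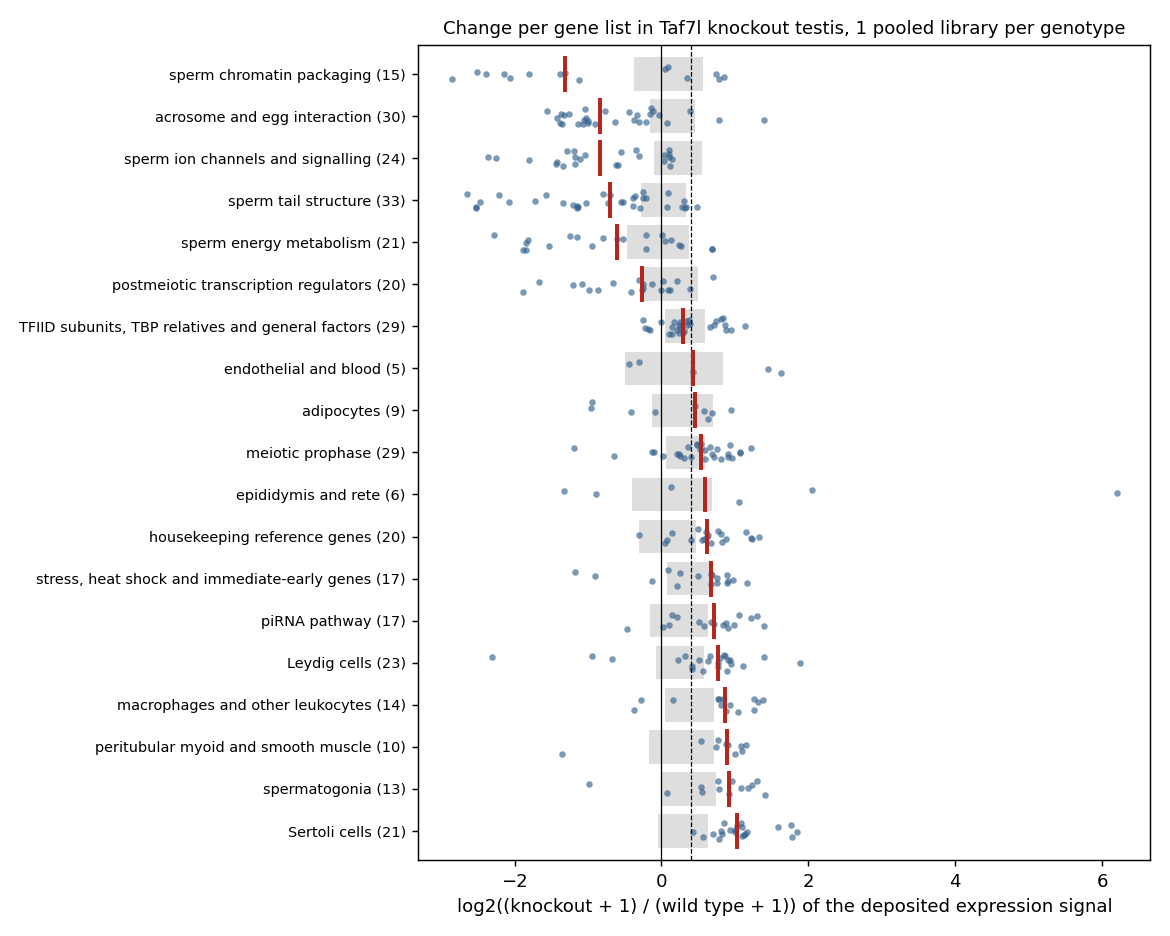
Log2 change of each member of 19 gene lists in Taf7l knockout against wild-type testis (x axis, pseudocount 1; number of measured members in brackets); points are genes, red bars list medians, grey bands the central 95% of medians of random lists matched on mean expression, the solid line 0 and the dashed line the median of all genes, 0.40. The median is -1.32 for sperm chromatin packaging and 1.03 for Sertoli cells, and Crisp1 lies at 6.21 in the epididymis list.

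Markers of spermatogonia and genes of the piRNA pathway lay above their matched lists. Of 22 spermatogonial markers 13 reached the mean of 1, and Zbtb16, Gfra1 and Sall4 were among those that did not. Of the 13 measured markers, 5 were at least 2-fold higher, with a median of 0.92, or 0.52 relative to all genes, at percentile 99.96. Dazl, an RNA-binding protein gene of germ cells, rose from 12.3 to 34.5, while Dmrtb1 had 288 and 304 and Pou5f1 5.43 and 2.26. Of 17 genes of the piRNA pathway, which silences transposons, 4 were at least 2-fold higher, with a median of 0.72, or 0.32 relative to all genes, at percentile 99.59. Mov10l1, its RNA helicase, rose from 28.8 to 77.4, whereas Mael had 497 and 536 and Gtsf1 428 and 309. After rescaling none of the spermatogonial or piRNA members was at least 2-fold higher.

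Meiotic prophase genes had a median of 0.53, or 0.13 relative to all genes, at percentile 91.9. With a pseudocount of 0.1 the median was 0.73 at percentile 98.65. Over the 18 members with a mean of at least 5 it was 0.39, or 0.04 relative to all genes, at percentile 75.2. Of 29 members, 3 were at least 2-fold higher and 1 lower. Tex12 and Syce2, both of the synaptonemal complex, went opposite ways: Tex12 rose from 6.05 to 15.4 and Syce2 fell from 71.0 to 30.4. After rescaling no member was at least 2-fold higher and 2 were lower. Hspa2 had 353 and 422. The list of TFIID subunits and general transcription factors had a median of 0.29, or -0.11 relative to all genes, at percentile 35.1. Polr2b was its only member past 2-fold with pseudocount 1, with 15.1 and 34.5, and was within 2-fold after rescaling. Without the pseudocount Taf1, Taf4a and Gtf2e1 were also past 2-fold higher. Taf9 had 205 and 245 and Gtf2a1l 165 and 138. The small list of Taf7l and its relatives had a median of 0.33, or -0.07 relative to all genes, at percentile 45.6.

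Median changes of the Sertoli, leukocyte and peritubular marker lists lay above those of their matched lists. Of 21 Sertoli cell genes, 12 were at least 2-fold higher and none lower, with a median of 1.03, or 0.63 relative to all genes, above all 10000 matched lists. After rescaling 4 were at least 2-fold higher. Drd4 rose from 8.29 to 32.4, Clu had 564 and 1076, and Tjp1 4.11 and 5.87. Macrophage and leukocyte markers had 5 of 14 members at least 2-fold higher and a median of 0.86 at percentile 99.94. C1qa, a complement component, rose from 8.58 to 24.1, C1qb had 12.2 and 23.4, and the class II gene H2-Aa had 5.33 and 3.90. Peritubular and smooth muscle genes had a median of 0.89 at percentile 99.91, with 4 of 10 members at least 2-fold higher. Acta2 rose from 30.0 to 67.8, but Actg2 fell from 200 to 77.4. After rescaling no member of the macrophage or muscle list was at least 2-fold higher.

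The Leydig cell list did not move uniformly. Cyp11a1, which encodes the enzyme that starts steroid synthesis from cholesterol, rose from 40.0 to 151. Ptgds, a prostaglandin D synthase gene, fell from 294 to 58.4, and the hormone gene Insl3 had 1686 and 1052. In all, 3 of 23 members were at least 2-fold higher and 1 lower, with a median of 0.77, or 0.36 relative to all genes, at percentile 99.99. After rescaling these counts were 2 and 3. In the endothelial and blood list only 5 genes reached the mean of 1. The globin genes Hba-a2 and Hbb-b1, whose reads near-identical copies can share, rose from 25.5 to 71.6 and from 13.8 to 44.7, and Vwf had 3.52 and 2.32. That list's median of 0.42 lay at percentile 47.8, and was 0.02 relative to all genes, with 1 member at least 2-fold higher after rescaling. At a mean of at least 5 only these 2 globin genes were left, with a median of 1.54 at percentile 99.4.

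Epididymal markers included the largest rise among all listed genes. Crisp1, which encodes a secreted protein of the epididymal duct, had 0.042 in the wild type and 75.9 in the knockout, a log2 change of 6.21 on the scale with pseudocount 1. Cst8, which testis also expresses, fell from 222 to 87.7. Of the 14 genes of this list only 6 reached the mean of 1. Of these 6 measured members 3 were at least 2-fold higher and 1 lower, and the median of 0.59 lay at percentile 91.3. Crisp1 and Adam7, the latter with 0.001 and 3.13, were among the higher members and were measured only through their knockout values. After rescaling 2 were higher and 2 lower, and the 3 members with a mean of at least 5 had a median of 1.05 at percentile 98.55. That median is the value of Spinlw1 alone, which had 31.7 in the wild type and 66.8 in the knockout. Adipocyte genes had no member past 2-fold on the scale with pseudocount 1, and a median of 0.45 at percentile 55.3. Their most abundant member Dgat2 had 126 and 65.2, Cidea 6.51 and 13.4, and Adipoq 8.44 and 3.86. Without the pseudocount Cidea and Fabp4 were past 2-fold higher and Adipoq past 2-fold lower. After rescaling 2 adipocyte genes were at least 2-fold lower. The median turned to -0.18, at percentile 12.15, over the 4 members with a mean of at least 5. Stress and immediate-early genes had a median of 0.68 at percentile 96.2. Bax rose from 6.84 to 16.5, Hspa1a, which has a near-identical copy, fell from 28.3 to 12.02, and Ddit3 had 103 and 109. After rescaling no stress gene was at least 2-fold higher and 2 were lower. Over the 10 stress genes with a mean of at least 5 the median was 0.23, at percentile 30.55.

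Housekeeping reference genes had a median of 0.62, or 0.22 relative to all genes, at percentile 99.89. Of 20 members 4 were at least 2-fold higher, and none was after rescaling. Tubb5 rose from 28.9 to 73.8, and Eef1a1 had 1174 and 1719.

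The largest changes by the rule of size were mostly small RNAs. All 12 of the largest decreases and 8 of the 12 largest increases were microRNA or small nucleolar RNA genes with spans of 57 to 91 bp, each listed at 0 in the other library. Their standard deviation over parts of the library was 2.67 to 8.00 times the mean. Snord69 had 351 and 0, and Snord66 0 and 275. Crisp1, the beta-defensin gene Defb28, Cd52 and Spink8 were the other 4 increases. Defb28 (chromosome 2, 152343990 to 152347183, mm9) had 0.183 and 49.6, Cd52, a glycoprotein gene of leukocytes and of the epididymal duct, 3.17 and 160, and Spink8 0.44 and 36.1.

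A filter chosen after the values were seen used the library with the higher signal of each gene. It kept genes whose standard deviation over parts there lay below the mean, which held for 12228 genes. Of these 866 were at least 2-fold higher and 856 lower. The largest decreases then were Prm2 and 1700012A03Rik, the latter with 187 and 25.1, followed by Adc with 106 and 14.0 and Gm614 with 44.9 and 5.55. Smcp, Odf1, Spata18, Prm1, Oaz3 and Tppp2 were also among the first 12. Odf1, an outer dense fibre gene of the tail, fell from 1796 to 312 and Oaz3 from 1521 to 273. Among the increases the filter placed Defb2, listed at 0 in the wild type and at 23.7 in the knockout, Wfdc15b with 0.007 and 17.3, Npy with 0.05 and 14.4, and Gpx3 with 2.88 and 51.7.

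**Figure D2:**
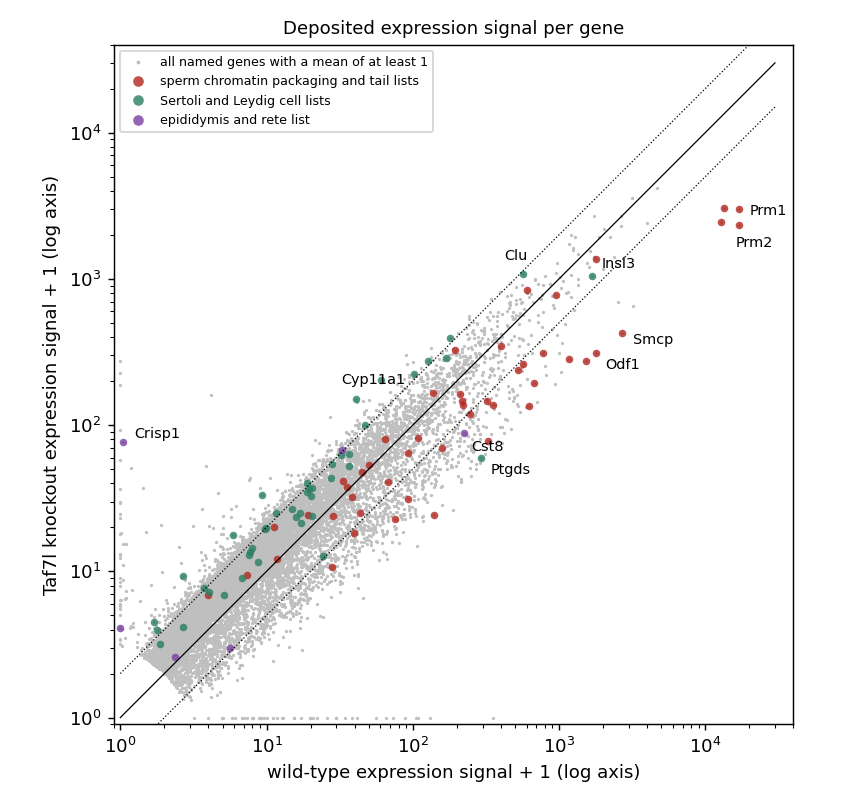
Deposited expression signal plus 1 of each named gene in wild-type (x axis, log scale) and Taf7l knockout testis (y axis, log scale), 1 pooled library each; grey points are all genes with a mean of at least 1, coloured points are listed genes, the solid line is equality and the dotted lines 2-fold. Prm1 lies at signals of 17005 and 2991, and Crisp1 at 0.042 and 75.9.

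The X chromosome held a larger share of lower genes than the autosomes. Of 497 X-linked genes, 87 were at least 2-fold lower, 17.5% (95% Wilson interval 14.4 to 21.1), against 6.88% (6.44 to 7.34) of 11926 autosomal genes. Draws of genes matched on mean expression gave a median of 4.83% (central 95%, 3.02 to 6.64). At least 2-fold higher were 58 X-linked genes, 11.7%, and 7.18% of autosomal genes. Draws matched on mean expression gave 6.24% (4.23 to 8.45) for the X-linked genes. The X-linked median of 0.41 was at percentile 7.45 of matched draws. With genes of a mean of at least 5, the X-linked and autosomal shares were 38.3% and 9.35% for lower genes and 20.9% and 8.68% for higher genes. After rescaling the lower shares were 25.2% and 12.2%, and the order of the higher shares turned, with 0.604% of X-linked and 1.05% of autosomal genes. Of 8 Y-linked genes 2 were lower and 1 was higher.

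TAF7L was assigned to the promoter class of many expressed genes. Of 55419 transcripts, 16039 had a TAF7L promoter score above 0 and 29658 a Pol II promoter score. Among the 12432 expressed genes these were 6847 genes, 55.1%, and 10778 genes, 86.7%. The scores are the authors' and have no stated definition. Their median over genes with a score was 71.7 for TAF7L and 374 for Pol II. Among these expressed genes the highest TAF7L promoter score was at Taf5, which encodes a TFIID subunit (chromosome 19, 47142237 to 47157969, mm9), with 929, beside a Pol II score of 1050. Gga3 and Mrps7, whose scores were identical, had 676, Cops6 652, Pcif1 531, Dcaf8 526, Sfi1 516, Nsfl1c 493 and Gm16517 488. Of the genes named here, Mrps7 and Nsfl1c were at least 2-fold higher in the knockout library, and within 2-fold after rescaling. The IgG library had no column of its own, so no background level is given.

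Promoters of the genes named above differed in TAF7L. Prm1, Prm2, Smcp, Odf1, Oaz3, Gapdhs and Spz1 had a TAF7L promoter score of 0, with Pol II scores of 871, 714, 259, 225, 313, 221 and 326. Most of these genes had TAF7L scores in the other classes. Of all expressed genes 33.8% had a proximal and 53.6% a distal TAF7L score. Equal scores below can be the same signal assigned more than once. In the proximal class Oaz3 had 187, Gapdhs 56.3, Prm2 45.8 and Prm1 37.3. In the distal class Spz1 had 97.9, Prm1 and Prm2 93.4 each, Oaz3 79.2 and Gapdhs 56.3. Smcp and Odf1 had 0 in all 3 classes. Tssk3 and Spata18, which also fell, had TAF7L promoter scores of 72.8 and 62.6. Meig1, Ldhc, Mael and Dazl had TAF7L promoter scores of 142, 104, 153 and 157. Of the piRNA list 17 of 17 measured genes had a TAF7L promoter score, and of the TFIID list 26 of 29. Sertoli and Leydig cell lists had 2 of 21 and 2 of 23, and the sperm chromatin packaging list 4 of 15. Of X-linked genes 4.43% (2.94 to 6.61) had a TAF7L promoter score and 56.3% a Pol II score, against 57.2% and 88.0% of autosomal genes. Draws matched on the Pol II score gave 17.3% with TAF7L (14.9 to 19.7).

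TAF7L and Pol II promoter scores occurred together. Of the 6847 genes with TAF7L, 6824 also had Pol II, 99.7%, against 70.8% of genes without TAF7L. Of Pol II genes 63.3% had TAF7L. Independent lists of these sizes would share 5936 genes. Across genes with both, Spearman's rho of the scores was 0.591 and Pearson's r of their log2 values 0.571, over genes that are not independent replicates. The share with TAF7L increased from 3.71% to 98.7% between the lowest and the highest of 10 equal groups of Pol II scores. The median wild-type signal was 9.79 for genes with TAF7L and 4.07 for genes without. When only genes with a score at or above the median of each list were kept, 89.4% of TAF7L genes had Pol II.

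Genes that were lower in the knockout seldom carried a TAF7L promoter score. Of 909 genes at least 2-fold lower, 216 had one, 23.8% (95% Wilson interval 21.1 to 26.6). Draws matched on wild-type expression gave 64.9% (central 95%, 62.05 to 67.8). Pol II scores were also fewer, 73.0% against 91.6%, and draws matched on the Pol II score gave 28.9% with TAF7L (27.1 to 30.9). Draws matched on both gave 30.3% (28.6 to 32.0). Of 915 genes at least 2-fold higher, 38.7% had TAF7L, against 53.7% (50.7 to 56.5) in draws matched on expression and 45.7% (43.7 to 47.8) in draws matched on the Pol II score. Seen from the promoters, 3.15% of genes with TAF7L were at least 2-fold lower, against 18.9% (18.0 to 19.7) in draws of genes without TAF7L matched on wild-type expression. For genes at least 2-fold higher the shares were 5.17% and 9.80% (9.14 to 10.5). The contrast was not particular to TAF7L. Of genes with a Pol II promoter score 6.16% were lower, against 22.6% (21.9 to 23.3) in matched draws of genes without Pol II. Higher were 6.97% and 8.41% (7.90 to 8.91). The draws without TAF7L were not matched on the Pol II score. These intervals describe draws of genes within single libraries and are no test of the genotypes. Keeping only TAF7L promoter scores at or above their median lowered the share of lower genes with TAF7L to 9.68%, against 35.2% in matched draws.

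**Figure D3:**
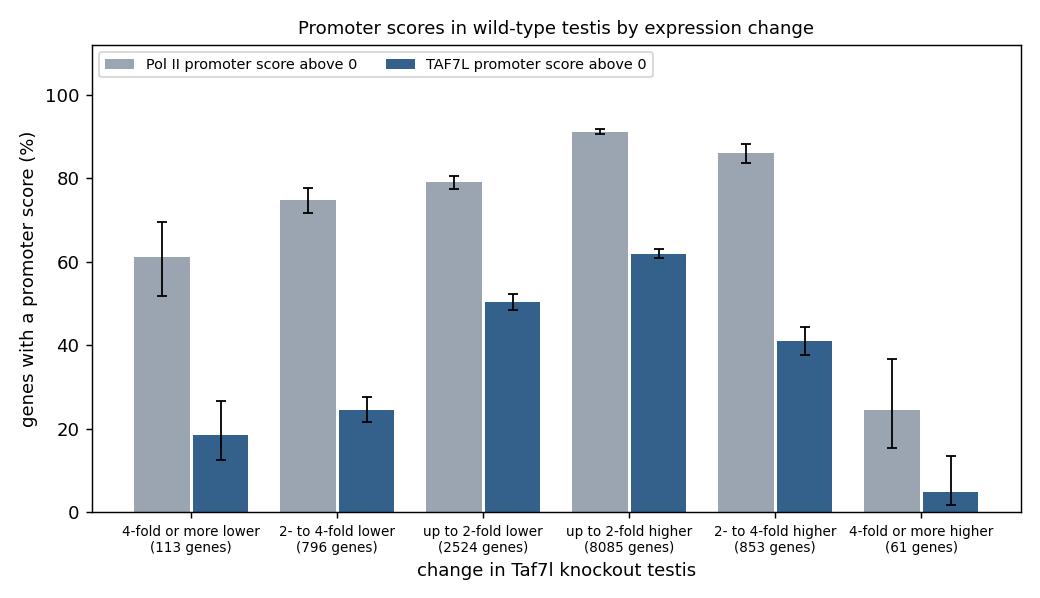
Percent of genes with a promoter score above 0 for Pol II (grey) and TAF7L (blue) in wild-type testis (y axis), by class of expression change in Taf7l knockout testis (x axis, number of genes in brackets); error bars are 95% Wilson intervals over genes. TAF7L is at 18.6% of genes 4-fold or more lower and at 61.9% of genes up to 2-fold higher.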

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

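The tests of spermatid share, of scaling, of values that rest on a few parts, of the general rise of other transcripts, and of duct genes nearly absent from the wild-type library were chosen after the results they concern had been seen. The tests of promoter loss, of the first duct list, of Pol II scores and of X-linked genes were written before, but the reading of promoter loss as open and the draws matched on both measures came after.

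Transcripts without a gene name stood outside the comparisons. Of 2107 such transcripts with a mean of at least 1 and a standard deviation over parts below the mean, 94 were at least 2-fold higher in the knockout library. A further 283 were at least 2-fold lower, and the median log2 change was 0.12. The transcripts drew attention as a signal in data the comparisons had not used, and no explanation was tested.

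Spermatid genes were lower in the knockout library. The test of the scaling of the deposited values decided nothing. Rescaling to a median change of 0 lowered every knockout value, so the sperm chromatin packaging median of -1.32 could only fall, to -1.81. A single factor moves all lists nearly alike. It therefore cannot give the distance between this list and the Sertoli cell list, which had a median of 0.60 after rescaling. Loss of TAF7L from the promoters of the genes that fell stays open: 23.8% of them had a TAF7L promoter score, below the 62.05% that marks the lower end of draws matched on expression and the 27.1% of draws matched on the Pol II score, but that bound took a score of 0 as no TAF7L, while the share of genes with a score ran from 3.71% to 98.7% over groups of Pol II scores, so that a weak signal can be listed at 0. A lower share of late spermatids in the knockout tissue stays open: the medians of the spermatogonial, Sertoli, Leydig, peritubular and macrophage lists lay within 0.26 of each other, a range that 30.3% of shuffles of their genes among the lists reached, but with the meiotic prophase list added the range was 0.50, which 4.46% reached. The loss of Taf7l itself, through cell makeup or through sites the promoter scores do not reach, also stays open and was not tested apart from it.

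Epididymal transcripts appeared in the knockout library, and the tables argue against values that rest on a few parts, with a median ratio of standard deviation to mean of 0.52 over 15 beta-defensin, Wfdc and Spink genes. The general rise of transcripts of cells other than spermatids stays open. The 32 measured genes of these families had a median of 1.90, against 0.77 to 1.03 in draws of as many somatic marker genes. The 26 outside the largest changes had a median of 1.09, against 0.73 to 1.05. However, the families were picked after their top members were seen. The 16 genes under 1 in the wild type were measured only through their knockout values. The 16 at 1 or more there had a median of 0.32. Carry-over of epididymal tissue went against its test written before: 0 of 13 duct epithelium genes with a knockout value of at least 0.5 rose past the threshold of 2.03, but 8 of the 13 were already at 1 or more in the wild type, and only 2 under 1 there could have passed on the scale with pseudocount 1, so the test decided nothing. In the test chosen afterwards, 7 of 9 duct genes under 0.5 in the wild type were over 4 times higher in the knockout, against at most 22.2% in the central 95% of draws matched on the wild-type signal, although only 5 of the 7 had a knockout mean above its standard deviation, and 0 of the 9 duct genes at 0.5 or more were 2 times higher. Among genes of the proximal epididymis, Adam7 had 0.001 and 3.13, whereas Lcn5 and Lcn8 had 0.058 and 0.014 in the knockout, so that carry-over stays open as a hypothesis, as does expression in the knockout testis itself, which was not tested.

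Genes that fell seldom carried a TAF7L promoter score, 23.8%. The tables argue against their lower Pol II promoter scores as the whole cause, by a small margin, since draws matched on these scores had a lower end of 27.1% and draws matched on these scores and on expression one of 28.6%. Matching on the Pol II score besides expression lowered the drawn share from 64.9% to 30.3%, so most of the gap went with the Pol II score. Since both scores rise together, whether Pol II was the cause of this part was not tested. X-linked genes among those that fell are also argued against as the whole cause, since 26.1% of the autosomal genes that fell had TAF7L, below 63.4% at the lower end of draws matched on expression and below 30.0% at that of autosomal draws matched on the Pol II score. The score has no stated definition and the IgG library no values, so weaker TAF7L signal under a calling threshold stays open, as does the makeup of the wild-type tissue by cell type.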

How the results depend on the processing

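The summed and median transcripts, the filter on the spread over parts, the proximal class and the class of the expressed transcript were chosen after the data were seen. Counts of genes at least 2-fold higher and lower, 915 and 909 as reported, were 238 and 576 with a pseudocount of 5, 4416 and 1634 at 1.5-fold, 104 and 264 at 3-fold, and 128 and 1583 after rescaling to a median of 0. The count of higher genes was 2036 with a pseudocount of 0.1 and 355 after rescaling to the upper quartile. These moves follow from how each setting is built. Shares of X-linked genes lower and higher were 23.5% and 32.0% with a pseudocount of 0.1, 38.3% and 20.9% at a mean of at least 5, and 25.2% and 0.604% after rescaling. The autosomal shares were 8.53% and 15.7%, 9.35% and 8.68%, and 12.2% and 1.05%. Scores at or above the median of each list left 3434 TAF7L and 5398 Pol II genes, by construction, and 89.4% of the former had Pol II. The share of lower genes with a TAF7L promoter score was 9.68% with those scores, 35.3% with the proximal class added and 19.3% with the expressed transcript alone. It was 29.6% at 1.5-fold and 32.3% after rescaling, and in each case lay below the central 95% of matched draws. The settings of scores, class and transcript remove or add scores by construction. Medians of their matched draws moved alike, to 35.2%, 72.2% and 56.8%. The cause of the moves at 1.5-fold and after rescaling was not tested. Gene lists below and above the central 95% of random lists numbered 5 and 7 as reported and after rescaling, 5 and 8 with a pseudocount of 0.1, and 5 and 9 at a mean of at least 5. Most named genes past 2-fold were picked for the size of their change, which favours their staying past it. Of 69 named genes past 2-fold, 69 stayed past it in the same direction with summed and with median transcripts. With a pseudocount of 5, 63 did, and 65 after upper-quartile and 57 after median rescaling. With a pseudocount of 0.1 all 69 did by construction, since a lower pseudocount only enlarges a change. No value of a called gene changed sign, which the pseudocounts and the rescaling could not bring about for genes past 2-fold. Low signals limit the precision of single genes, and without replicates no library could be left out. Overlaps of peak positions, distances of 500 bp or 5 kb, densities, the authors' significance calls and a status filter were not run, since the tables used here hold none of these columns.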

Other observations

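Gene families were grouped by symbol after the data were seen, and their medians are given as values. Ribosomal protein genes had a median log2 change of 0.54 over 78 genes, or 0.13 relative to all genes, and mitochondrial ribosomal protein genes 0.62 over 76, or 0.22 relative. Both lay above the central 95% of matched lists, at percentiles 100 and 99.93, and 91.0% and 84.2% of their genes had a TAF7L promoter score. Collagen genes had a median of 1.23 over 19 genes, with 10 at least 2-fold higher and 3 lower, and 8 higher and 5 lower after rescaling. None of them had a TAF7L promoter score. Of 443 measured RIKEN clones of the series cloned mostly from testis, 173 were at least 2-fold lower and 9 higher. Their median was -0.73, and 39.7% had a TAF7L promoter score. Of 17 Spata genes 7 were at least 2-fold lower, with a median of -0.83 at percentile 0.08, and 12 of the 17 had TAF7L. Olfactory receptor genes, 12 in all, had a median of -0.82.

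Secreted protein families differed within themselves. Of 18 beta-defensin genes 11 were at least 2-fold higher and 1 was lower, with a median of 2.11, or 1.71 relative to all genes. Most of the higher genes were under 1 in the wild type and were measured only through their knockout values. Over the 16 beta-defensin, Wfdc and Spink genes at 1 or more in the wild type the median was 0.32, below the 0.40 of all genes. Defb19, abundant in wild-type testis, had 507 and 875, while Defb37 had 0.076 and 5.43. Of 10 Wfdc genes 7 were at least 2-fold higher, with Wfdc10 at 88.6 and 303. The kallikrein genes went both ways, with Klk1b27 at 3.68 in the wild type and 33.5 in the knockout and Klk1b8 at 61.7 and 12.6, although reads can be shared among these close paralogues. Among seminal vesicle and prostate genes, a list written after the epididymal transcripts were seen, Svs5 had 3.74 and 9.69, Svs2 0.004 and 0.014, and Pbsn was listed at 0 in both libraries.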
